A study of Hafnia alvei with 6 samples.

How the data were processed

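RNA-seq libraries of Hafnia alvei H4 were compared between 3 untreated control samples and 3 samples treated with 31.25 µM TF3, grouped by their titles and treatment labels. Per the labels, total RNA was extracted from pelleted cells and libraries followed standard Illumina protocols. Bowtie2 2.2.3 and HTSeq 0.6.1 are named in the submitters' processing notes, without their roles. The genome build, the annotation, the strand setting and how small RNAs and transcripts outside the locus tag numbering were defined are not given in the sources used here. Reads of overlapping or antisense features and of near-identical copies therefore cannot be told apart. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

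The deposited values are FPKM, per the file headers, with one column per sample and 4636 features. In every file the values of a feature were whole multiples of a step set by one length per feature and one scale per library. From these steps a whole length in bp and whole read numbers were recovered for 4606 of the 4606 features with a value above 0 (100%, tolerance 0.02 of a read plus a relative 3e-08), while 30 features were listed at 0 in all 6 libraries. Of the recovered lengths of annotated loci, 92.4% were multiples of 3. The recovered numbers are the smallest that give the values, so totals are minimums; about 1.70% of features would be expected to have read numbers with a common divisor and thus to be understated. Depth ranged from 5946516 to 7122980 reads per library. The scale of each library was proportional to a median-of-ratios size factor computed from the recovered reads, within a relative deviation of 4.35e-11. By their values, the FPKM were thus already scaled between libraries and not only to library totals, and they were used as deposited.

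The design fixed before the data were examined assumed read counts and named a fallback for FPKM, which was used. Values were transformed to log2(FPKM + 1). Features were kept where at least 3 libraries reached 1 FPKM, which left 4469 features and removed 167. Groups were compared with limma-trend (limma 3.58.1, R 4.3.3), with group as the only term, empirical Bayes at its defaults and Benjamini-Hochberg adjustment. Features with an adjusted p under 0.05 were called changed, and an absolute fitted log2 fold change of at least 1 was added for changes of at least 2-fold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low features. The median standard error of a log2 fold change was 0.117, and the median residual SD was 0.143.

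The rule for named genes, written before the data were examined, took the largest changes among genes with a symbol, the members of fixed gene lists and the genes with the smallest p-values. The files do not pair IDs with symbols or products, so the parts of the rule that need symbols, the fixed lists and their set tests were not applied. The named loci are the 2 that rose and the 2 that fell with the smallest p-values. This departed from the part of the rule on the smallest p-values of all, which needs no symbols. That part would also have named ERL64_RS05130 (log2 fold change 8.18, limma-trend adjusted p = 5.31e-11). rRNA and tRNA loci were not identified and were not removed.

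Libraries of the same group were compared for duplication by a chi-square test of recovered reads over features with at least 10 reads; the ratio of chi-square to degrees of freedom ran from 4.74 to 10.5, so no pair agreed within sampling noise. Runs of consecutive tags, which step by 5, and their shuffles, correlations between neighbours and exact permutation and Fisher's tests were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

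The procedure was tested on simulated data drawn for the TF3 against control comparison, with 200 changed features among 4477 tested, 50 at each fold. It called 76% of features changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 14 of its 199 calls were false (7.04%). All simulated features shared 1 dispersion, 0.00125, the median of control features with many reads. Changed features were drawn only from those above a minimum read number, and fewer changed than were called in the real data. These rates may therefore be better than those for the real data. Recovery of simulated reads was exact for 98.9% of 4597 features and exact up to a common divisor for 100%.

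Alternatives tried were pseudocounts of 0.1 and 5 FPKM, no filter and a filter at 10 RPM (recovered reads normalised to depth) in 3 libraries, other scalings between libraries, limma-voom on recovered reads, robust empirical Bayes, a replicate term, leaving out each library in turn and tests against a 2-fold or 1.2-fold minimum.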

Results

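The transcriptome of Hafnia alvei H4 was measured by RNA-seq after culture with or without theaflavin-3,3′-digallate (TF3). H. alvei is an enteric Gram-negative bacterium that also occurs on refrigerated foods. TF3 is a polyphenol of black tea, used here as an inhibitor of quorum sensing, the cell-to-cell signalling by which bacteria adjust gene expression to population density. The treated group held 3 libraries of bacteria given 31.25 µM TF3, a dose below the one that inhibits growth. The control group held 3 libraries of untreated bacteria. Growth is not among the values used here, so an effect of TF3 on growth was not tested. The values were FPKM, a read abundance normalised to feature length and library depth, for 4636 features. Of these, 4319 were loci with a numbered locus tag, 24 were small RNAs and 293 were transcripts outside the locus tag numbering. Whole reads recovered from the FPKM gave a depth of 7112966, 6803560 and 6845812 reads in control replicates 1 to 3 and of 5946516, 7016657 and 7122980 reads in TF3 replicates 1 to 3. The files do not pair the locus tags with gene names, so loci are given by tag, by class and by their place in the tag order, and no quorum sensing gene was identified.

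The question was which transcripts TF3 changed. Features rose and fell in near equal numbers at the deposited scaling, a balance that this scaling partly sets because it places the middle feature near no change. Of 4469 features tested, 1552 changed (34.7%), 768 of them higher and 784 lower in TF3 (limma-trend, Benjamini-Hochberg adjusted p under 0.05). Of these, 337 changed at least 2-fold by their fitted value, 176 upward and 161 downward. In a test that the change exceeded 2-fold beyond its error, 158 features were called. When the libraries were scaled to total recovered reads instead, the split was 546 higher and 907 lower, and 37.6% rather than 49.5% of the calls were higher. With the single most abundant feature left out of those totals, the split was 788 higher and 777 lower, and 50.4% of the calls were higher. The separation exceeded the spread between replicates. Pearson correlations of log2 FPKM across features, which are not independent, were 0.986 to 0.990 between libraries of the same group and 0.937 to 0.942 between libraries of different groups. The first principal component held 76.0% of the variance and separated the groups, and the second held 7.52%. In 2143 features (48.0%) all 3 libraries of one group lay above all 3 of the other, against 10% by chance for 3 against 3.

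The 2 loci with the smallest p-values among those that rose were ERL64_RS15875 and ERL64_RS05120. ERL64_RS15875, a locus of 627 bp, rose from 32.7 ± 1.51 FPKM in control to 2757 ± 48.7 FPKM in TF3 (SD, n = 3 per group), a ratio of 84.4. Its log2 fold change was 6.36 with a standard error of 0.048 (limma-trend adjusted p = 2.93e-11), and it rested on 134 to 156 reads per control library and 9816 to 12668 per TF3 library. ERL64_RS05120, of 1038 bp, rose from 3.36 ± 0.457 to 4359 ± 132 FPKM (SD, n = 3 per group), with 21 to 28 reads per control library and 26485 to 31620 per TF3 library. The log2 fold change of ERL64_RS05120 was 9.97 with a standard error of 0.080 (limma-trend adjusted p = 2.93e-11), on a log2(FPKM + 1) scale that understates the change of loci this low in control. The 2 loci with the smallest p-values among those that fell were abundant in control. ERL64_RS04370, of 579 bp, fell from 6782 ± 316 to 427 ± 29.2 FPKM (SD, n = 3 per group), 15.9-fold lower in TF3, with a log2 fold change of -3.99 and a standard error of 0.059 (limma-trend adjusted p = 1.06e-09). ERL64_RS13345, of 1434 bp, fell from 1686 ± 76.8 to 359 ± 6.46 FPKM (SD, n = 3 per group), 4.70-fold lower, with a log2 fold change of -2.23 and a standard error of 0.044 (limma-trend adjusted p = 9.25e-09).

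**Figure D1:**
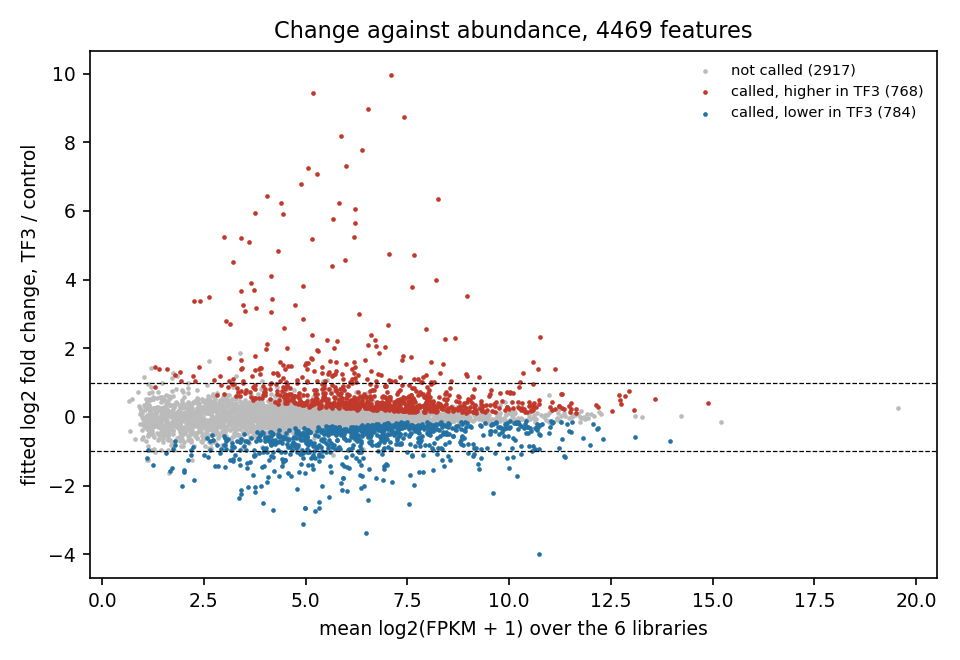
Each point is one of 4469 features, with its mean log2(FPKM + 1) over the 6 libraries on the horizontal axis and its fitted log2 fold change, TF3 over control, on the vertical axis. Red points are the 768 features called higher in TF3, blue points the 784 called lower and grey points those not called, and the dashed lines mark a 2-fold change; rises extend to 9.97 and falls to -3.99.

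Rises reached larger folds than falls. At 4-fold or more, 67 features were higher and 28 lower in TF3. At 8-fold or more, 48 were higher and 3 lower, and at 16-fold or more, 31 were higher and 0 lower. In 15 features the rise was at least 64-fold. A group of 18 features had a mean under 5 FPKM in control and of at least 50 FPKM in TF3, and 0 features showed the converse. Among the 100 features with the highest mean level, 33 rose, 25 fell and 42 were not called. Of these, 6 rose and 3 fell by at least 2-fold.

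Large changes fell on consecutive locus tags. Runs of at least 3 consecutive tags, each changed at least 2-fold in the same direction and past the adjusted threshold, held 149 of the 302 locus tags that changed at least 2-fold (49.3%). There were 33 such runs, 17 rising with 83 loci and 16 falling with 66 loci, and the longest held 9 loci. When the calls were shuffled over the tags 10000 times, the median number of loci in runs was 0 and the highest was 15. Runs were defined after the values had been seen. Tag order stands in for gene order, because strand and contig ends were not used here. The rising runs together took 0.429% ± 0.0066 of the reads in control and 3.00% ± 0.051 in TF3, and the falling runs 1.86% ± 0.057 in control and 0.634% ± 0.013 in TF3 (SD, n = 3 per group). Those loci had been selected for their change, so the shares were not tested.

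**Figure D2:**
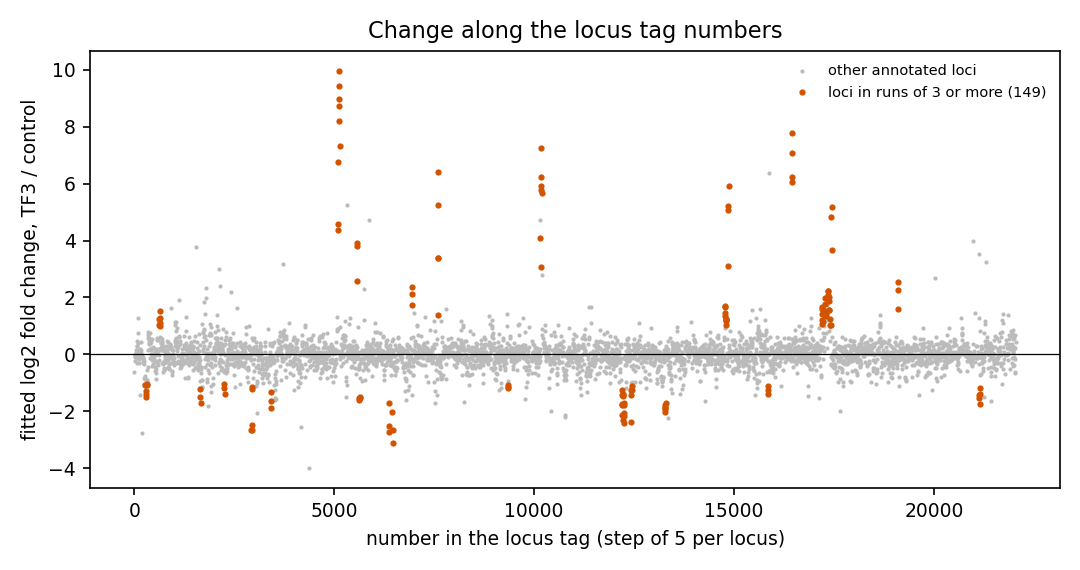
Fitted log2 fold change, TF3 over control, of each tested annotated locus (vertical axis) against the number in its locus tag (horizontal axis, step of 5 per locus). Orange points are the 149 loci in 33 runs of at least 3 consecutive tags changed at least 2-fold in one direction and grey points are the other loci.

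The run with the largest median change held 9 loci, ERL64_RS05120 among them, over a summed length of 8505 bp. Its loci lay between 0.404 and 12.2 FPKM in control and between 230.1 and 4359 FPKM in TF3, with log2 fold changes of 4.39 to 9.97 and a median of 8.18. A run of 4 loci rose by a median log2 fold change of 6.65, a run of 7 loci by 5.77 and another run of 4 loci by 5.15. A second run of 9 loci rose less, by a median log2 fold change of 2.02. Of the 48 features that rose at least 8-fold, 33 lay in rising runs. So did 17 of the 18 features that went from under 5 to at least 50 FPKM. The 48 and the 18 also include transcripts outside the tag numbering, which cannot lie in a run. The 3 falling runs with the largest median falls held 3, 3 and 5 loci, with median log2 fold changes of -2.65, -2.51 and -2.47. Longer falling runs of 8 and 6 loci had medians of -1.74 and -1.86.

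**Figure D3:**
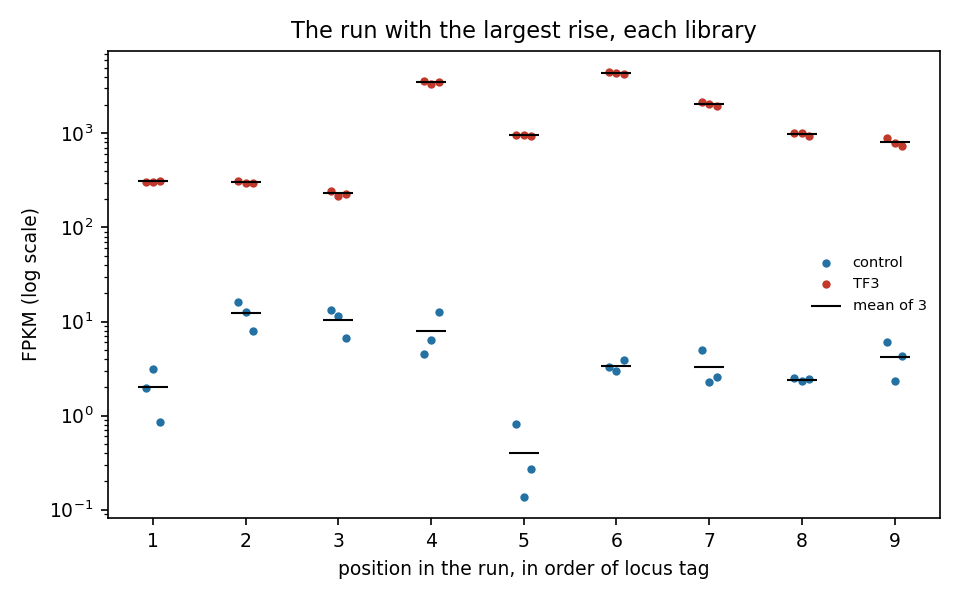
FPKM of each library (log scale, vertical axis) at the 9 consecutive loci of the run with the largest median rise, in order of locus tag (horizontal axis). Blue points are the 3 control libraries, red points the 3 TF3 libraries and black bars the group means; control means lie between 0.404 and 12.2 FPKM and TF3 means between 230.1 and 4359 FPKM.

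Some runs of one direction stood close together. Stretches were drawn from the first to the last locus of such runs. Run members had been selected for their change, so the counts and medians below largely restate that selection. In a stretch of 50 loci, 30 of them in 6 rising runs, 42 loci rose, 35 of them at least 2-fold, and 0 fell, with a median log2 fold change of 1.40. In a stretch of 21 loci, 13 of them in 3 rising runs, 15 loci rose and 1 fell, with a median log2 fold change of 1.21. In a stretch of 15 loci with 2 falling runs, 14 loci fell, all of them run members, with a median log2 fold change of -1.75. All 8 loci of another stretch, 6 of them in 2 falling runs, fell, with a median of -1.08.

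Each class of features held both rises and falls. Among 4154 tested locus tags, 730 rose, 727 fell and 2697 were not called, and 158 rises and 144 falls were at least 2-fold. Among 291 tested transcripts outside the tag numbering, 35 rose, 55 fell and 201 were not called. Their balance of rises to falls was lower than that of the locus tags, with an odds ratio of 0.634, but did not pass the threshold after adjustment over the 2 comparisons made (Fisher's exact test, two-sided p = 0.0396, Benjamini-Hochberg adjusted p = 0.0793). This call depended on the setting. The odds ratio was below 1 in all 18 alternatives, from 0.388 to 0.797, and passed the threshold in 6 of them, with adjusted p from 0.000153 to 0.531 over the 18 (Fisher's exact test, two-sided). Without control replicate 3 the odds ratio was 0.388, with 25 rises and 61 falls, and with limma-voom on recovered reads at the deposited scaling it was 0.503, with 34 rises and 63 falls. Their share of changed features, 30.9% against 35.1%, did not pass the threshold either (Fisher's exact test, two-sided p = 0.162), and passed it in 1 of the 18 alternatives, the filter at 10 RPM in 3 libraries (Fisher's exact test, adjusted p = 0.0134; RPM is recovered reads normalised to depth). Neighbouring transcripts are not independent, so these p-values are approximate. Of 24 small RNAs, 3 rose, 2 fell and 19 were not called. Under the filter at 10 RPM, 1 small RNA was called, and with a replicate term in the model 8 were called. That filter takes features out before the test, so small RNAs no longer called under it may not have been tested.

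A single feature of 364 bp took more reads than any other in these libraries, 26.7% ± 1.32 in control and 30.3% ± 1.71 in TF3 (SD, n = 3 per group). All 3 TF3 libraries lay above all 3 control libraries (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). In FPKM its log2 fold change was 0.25 with a standard error of 0.14, and it was not called (limma-trend adjusted p = 0.227). The small RNAs together took 0.896% ± 0.064 of the reads in control and 1.12% ± 0.095 in TF3 (SD, n = 3 per group; exact permutation test, two-sided p = 0.1).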

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

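The TMM and most-abundant-feature scalings, limma-voom at the deposited scaling, robust empirical Bayes and the tests against a fold minimum were chosen after the data were seen. The other settings were planned, but applying them to runs and to the balance of rises and falls outside the tag numbering was decided after the data were seen. The number of changed features lay between 1247 and 1681 over 18 alternatives, against 1552, and between 1247 and 1432 when one library was left out. Of the 1552 features, 1099 remained called in all 6 leave-outs, 453 were lost in at least one and 0 changed sign; of the 337 changed at least 2-fold, 322 remained. The number of runs lay between 29 and 35, and the 4 named loci kept their direction and their call under the same 18 alternatives. limma-voom on the recovered reads, which came out whole for 100% of features, called 1681 features, 1485 of them shared. Tested against a 2-fold minimum, 158 features were called, against 337, because that test asks that the change exceed 2-fold beyond its error. Small RNAs changed moved from 5 to 1 with a filter at 10 RPM and to 8 with the replicate block; the cause was not tested. The replicate block called 1445 features, 1389 of them shared. Same-numbered samples deviated from their group means with correlations of -0.018, 0.027 and -0.095. These values showed no pairing by number, which does not exclude that the samples were handled in pairs. The odds ratio of rises to falls outside the tag numbering, 0.634, passed the threshold in 6 of 18 alternatives: the filter at 10 RPM (0.562), limma-voom with TMM (0.549) and at the deposited scaling (0.503), the replicate block (0.592), without control replicate 3 (0.388) and without TF3 replicate 1 (0.519); the cause was not tested. The count-model tests planned for read counts, the removal of rRNA and tRNA and the gene lists were not run. With 21 to 28 control reads behind ERL64_RS05120, depth limits the precision of its control level.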

Other observations

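The tests of scaling and of neighbouring reads on runs, of few reads and of other splits of the libraries were chosen after the result was seen, as was the definition of runs; the others were set before. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split, the 1 of 10 that gave as many calls, gave 1552 changed features, 768 higher, 784 lower, 337 changed at least 2-fold, 90 changed transcripts outside the tag numbering and 5 changed small RNAs, and the highest of the other splits gave 0 for each. Every other split mixed control and TF3 libraries in both of its groups. The difference between control and TF3 then added to the spread within groups and lowered the calls. These splits therefore do not show how many calls noise alone would give.

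Large rises came in runs of consecutive locus tags. Chance placement of the calls gave at most 15 loci in runs in 10000 shuffles, against 149 observed in rising and falling runs together. The rises were also set against counting of one induced locus's reads in its neighbours. The other 66 loci of the 17 rising runs rose in FPKM by a median of 38.0% of the rise of their run's top locus. The median over runs was 39.0% (exact 95% interval 30.9% to 44.4%, above a bound of 25%). For the 43 loci not adjacent to the top locus, the median was 34.5%. Loci entered a run only with a rise of at least 2-fold. In runs with small folds and similar control levels, that alone forces a large share. An example is a run of 6 loci with log2 fold changes of 1.04 to 1.67 and control means of 29.3 to 48.2 FPKM. The bound therefore cannot decide for such runs. In the run with the largest rise the median was 20.1%, but a locus 2 tags from the top locus rose 3.68 times as much as the locus of 2118 bp between them (3.53 to 3.77 times in the 3 TF3 libraries). In 2 other runs the median lay under 25%, and there and in runs with small folds the explanation stays open. In 1 of these 2, the TF3 mean was 152.2 FPKM at the top locus, ERL64_RS07605. It was 48.8, 16.2 and 14.7 FPKM at ERL64_RS07600, ERL64_RS07595 and ERL64_RS07590, a decline with distance that such counting could give. Scaling between libraries moved the median log2 fold change of all features by at most -0.065, against run medians of up to 8.18. A candidate explanation is that most rising runs are operons, consecutive genes transcribed together, that respond to TF3; strand and gene names, which would test this, were not used here.

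Rises reached larger folds than falls. Counting error from few reads does not account for this: 60 of the 67 rises of at least 4-fold were still at least 4-fold between the nearest exact 95% Poisson limits of both groups' summed reads, 2.14 times all 28 falls of that size, and 16 of those falls were. These limits cover counting error alone. Libraries of the same group varied by more than that, with chi-square 4.74 to 10.5 times its degrees of freedom. Rises also outnumbered falls at 4-fold or more by a factor of at least 2.21 under each of the 4 other scalings. These scalings moved the median log2 fold change of all features by at most -0.065. They cannot show what a larger shift between the groups would do, which was not tested. A floor of measurement that hides large falls stays open. Among features changed at least 4-fold with a higher group mean of at least 64 FPKM, 74.6% were rises (50 against 17, exact 95% interval 62.5% to 84.5%), which passed the bound of 60% set beforehand, but that bound took features as independent, which loci in runs are not; with each run counted once the share was 71.8% (28 against 11, exact 95% interval 55.1% to 85.0%), and this stricter reading was adopted after the result was seen. At 8-fold or more with the same minimum level, 35 features rose and 3 fell.

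Neighbouring loci also shared changes too small to be in a run. Across loci under 2-fold, which are not independent, the fold changes of consecutive tags had a Pearson correlation of 0.326, against at most 0.063 in 10000 shuffles. It was 0.187 at 2 tags apart, 0.117 at 3, 0.062 at 5 and -0.0088 at 20. Over all tested loci it was 0.635 for consecutive tags and 0.023 at 20 tags apart. This is consistent with transcription of neighbouring genes in shared units; shared responses of separate transcripts, or reads that overlap 2 adjacent loci, were not tested for these small changes.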
